A study of Mus musculus with 15 samples.

How the data were processed

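RNA was measured on 15 one-colour expression arrays of primary muscle cells from C57BL/6 mice. Per the labels, myoblasts from pups of about 2 weeks were kept in 10% fetal bovine serum with basic fibroblast growth factor. Differentiation took 2 days in medium with 2% horse serum, and virus was added overnight at a multiplicity of infection of 100. Total RNA was extracted with TRIzol and column purification, and labelled with biotin. There were 5 groups of 3 arrays, which expressed GFP or isoform A1, A2, A3 or A4 of PGC-1α. The labels do not say whether the 3 arrays of a group come from separate cultures, so the p-values measure only the spread between these arrays.

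The deposited table holds 1 intensity per probe set and array for 45037 probe sets, on a linear scale from 0.45 to 18727.83. How the authors summarised, scaled or background-corrected these values is not given in the sources used here. Array medians lay close together, and the lowest number of values at exactly 1 on any array was 882 and the highest 1103. Probe sets were matched to gene symbols by the platform table. Of all probe sets, 34945 carried 1 symbol, 932 several, and 9160 none or were not listed. For each gene the probe set with the highest mean over the 15 arrays was kept, which gave 18193 genes, 9010 of them with more than 1 probe set. The 10092 probe sets without a single symbol were left out of the gene tests, because their signal cannot be assigned to 1 gene, and were tested only as an alternative.

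Intensities were transformed as log2 of the value plus 16, without further normalization. In R 4.3.3 with limma 3.58.1, 1 mean per group was fitted to all 15 arrays with empirical Bayes moderation of the variance. P-values were adjusted by Benjamini-Hochberg over all genes within each of 11 contrasts, and genes with an adjusted p below 0.05 were called. The contrasts were each isoform against GFP, each pair of isoforms, and A4 against the mean of the other 4 groups. The last one has no single group as control. A gene set a group apart when all 4 contrasts of that group passed with the same sign. Overlaps of calls were set beside the number that independent calls would share and beside simulated overlaps with the same GFP arrays. Fold changes come from the log2 scale with the added 16, so folds of dim genes are smaller than ratios of intensities.

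The 39 gene lists with 1152 members had been written before the data were examined, and 1068 members were measured. They were tested in 6 contrasts, the 4 against GFP and the 2 that set A4 against A1 and against the mean of the others. The test was limma camera with a preset correlation between genes of 0.01, repeated with a correlation estimated per list and with limma fry. Members were also adjusted over the list alone.

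Genes named in the text follow a rule also written before the data were examined. It takes, in 6 contrasts, the 8 largest rises and 8 largest falls among called genes whose arrays do not overlap between the groups. Among 3 against 3 arrays, chance alone gives such a separation in 10% of cases. It adds up to 4 called genes of each list by size of change, up to 8 genes per direction that set a group apart, and 16 genes fixed in advance. Clone names and predicted genes were left out. The text names fewer than the rule gives and skips some ranked higher, such as Mtmr3 above Ifit1 for A3. Genes named as changed in opposite directions also skip some with larger changes. Which genes were skipped was not fixed in advance. Of the fixed genes 15 were measured, and Mstn, which had no probe set in the platform table, was not analysed here. The comparison of a gene's probe sets, with a floor of 50 for the mean intensity of the others, was chosen after the data were seen.

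Precision is limited by the number of arrays. Among 4694 genes with a mean intensity of at least 500, the median coefficient of variation within groups was 3.71% to 5.72%. The procedure was tested for A4 over GFP on 10 simulated data sets with 200 changed genes each. Changes were planted only in genes brighter than the median intensity of every array, so recovery of dim genes was not tested. Recovery also depends on how many genes change, and the real contrast called 5429 genes. The recovery given here holds only for 200 changed genes. The procedure recovered 33.6% of genes changed 1.25-fold, 82.2% at 1.5-fold, 97.4% at 2-fold and 99.6% at 4-fold, with false calls at 5.47% of calls. Without any change it called on average 0 genes and 0 lists, and a list shifted by 0.2 on the log2 scale was called in 10 of 10 data sets. Genes were simulated independently of each other. The results for lists therefore do not hold for lists whose genes vary together, as they do in the real arrays.

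The alternatives were quantile normalization, median centring, an added value of 1 or 64, leaving out the dimmest genes (1 in 3), the mean of all probe sets of a gene, all probe sets on their own, only the groups compared, moderation with a trend and robust, array weights, the replicate number as a block, and leaving out each array in turn. For A4 against the others, the fit of only the groups compared used 1 pooled group of 12 arrays. After the data were seen, 1 alternative was added, which left out 279 of 6269 genes whose chosen probe set differed by over 2 times in fold from the mean of the others. For chance, arrays were regrouped in all 10 splits of each pair of groups, or in 100 regroupings of all 15 arrays.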

Results

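The experiment asked how 4 isoforms of PGC-1α, the transcriptional coactivator encoded by Ppargc1a, change gene expression in muscle cells, and which changes go with muscle hypertrophy. Mouse myotubes had been transduced with an adenovirus that expressed isoform A1, A2, A3 or A4, or green fluorescent protein (GFP) as the control. The labels record hypertrophy for A4 and none for the other 4 groups. Each of the 5 groups has 3 arrays, 15 in all, and the number of arrays limits the precision. Median intensity per array lay between 86.5 and 96.1, and 12.5% to 13.4% of the probe sets of each array read below an intensity of 16. Pearson's r between arrays, across genes that are not independent replicates, was 0.985 to 0.991 within groups and 0.960 to 0.988 between groups. The first principal component, with 31.5% of the variance, separated A1 from all other groups. The second, with 19.5%, separated A4 from the rest. On both, A2 and A3 lay close to GFP.

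**Figure D1:**
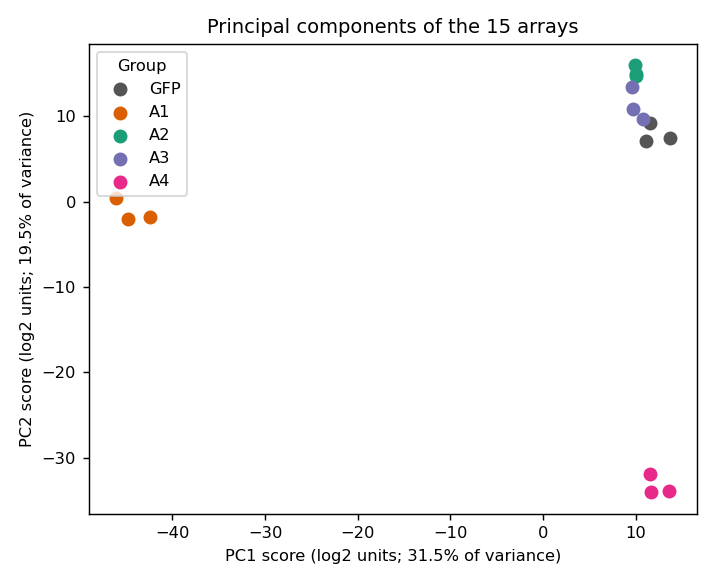
Scores of the 15 arrays on the first and second principal components of log2 gene values, 1 point per array, coloured by group; the first component holds 31.5% of the variance and the second 19.5%. The 3 A1 arrays lie between -46.0 and -42.4 on the first component, and the 3 A4 arrays between -34.0 and -31.9 on the second.

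The label of each group was first compared with the signal of the transduced gene. Ppargc1a is represented by 5 probe sets. The brightest read 11252 ± 1259 in A1 and 341 ± 29.6 in GFP (mean ± SD, n = 3), a 31.5-fold rise with a limma adjusted p of 6.5e-11. It read 238 ± 8.27 in A2, 245 ± 52.8 in A3 and 258 ± 9.27 in A4, and was called lower than GFP in all 3 (adjusted p = 0.027, 0.019 and 0.036). Each of these falls lost its call without single arrays and none was called for the mean of the 5 probe sets (adjusted p = 0.11, 0.24 and 0.39). Adjusted over all probe sets, as for the other 4 below, the fall in A4 was not called (adjusted p = 0.0503). The other 4 probe sets were lower in A1 than in GFP, and in the one with the largest fall the signal went from 140 ± 14.1 to 71.3 ± 12.5 (adjusted p = 0.00034). Among these 4, 1 rose in A4, from 151 ± 17.5 to 195 ± 13.6 (1.27-fold, adjusted p = 0.014), and none was called in A2 or A3. No Ppargc1a probe set thus showed a strong rise in A2, A3 or A4, and for these groups the labels could not be checked this way. The sequences of the transduced isoforms were not used here.

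**Figure D2:**
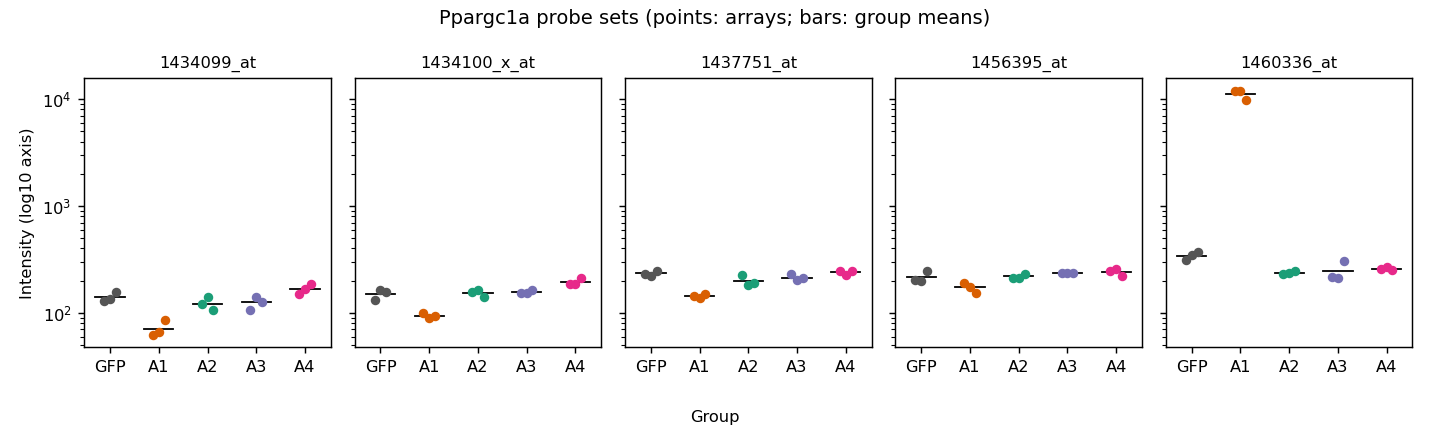
Intensity of the 5 Ppargc1a probe sets on each of the 15 arrays, on a log10 axis, with 1 point per array and a bar at the mean of each group. Only the brightest probe set in A1 stands far above GFP, at 11252 against 341.

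In A1 myotubes, genes of mitochondrial energy metabolism rose and genes of the contractile apparatus fell, though 2 of the 5 mitochondrial lists, the respiratory chain and the mitochondrial ribosome, missed the threshold with an estimated correlation (adjusted p = 0.055 each). Of 75 measured genes of the respiratory chain and ATP synthase, 73 rose and none fell. The same held for 18 of 20 genes of pyruvate oxidation and the TCA cycle, 24 of 29 of fatty acid uptake and oxidation, 26 of 31 of mitochondrial DNA, import and dynamics, and 46 of 53 of the mitochondrial ribosome. At the same time 23 of 26 genes of the embryonic and common sarcomere fell, as did 11 of 15 of the fast fibre sarcomere.

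Cox7a1, a muscle subunit of cytochrome oxidase, rose 5.72-fold (log2 2.52 ± 0.09, SE, n = 3, adjusted p = 5.4e-10), from an intensity of 679 ± 77.7 to 3942 ± 83.2 (SD). Ndufb10 rose 2.52-fold and Uqcrc2 2.22-fold. Among genes that feed the TCA cycle, Mpc1, a mitochondrial pyruvate carrier, rose 2.91-fold, Dlat 2.87-fold and Idh3a 2.70-fold. Cpt1a, which commits fatty acids to oxidation, rose 5.03-fold (log2 2.33 ± 0.08, adjusted p = 3.5e-10), and its 2 other probe sets rose as well (log2 2.08 and 1.88). Fabp3 rose 3.78-fold and Etfdh 3.05-fold, while another probe set of each moved far less (log2 0.33 and -0.03). The import factor Timm8a1 rose 4.32-fold and the ribosomal protein Mrpl47 4.04-fold, with log2 1.68 and 0.23 at its other probe sets. Among regulators of these genes, Perm1 rose 7.04-fold, the nuclear receptor Esrra 5.36-fold (log2 2.42 ± 0.09, adjusted p = 9.9e-10) and the deacetylase Sirt3 3.64-fold. Another probe set of Esrra gave log2 0.57 and another of Perm1 0.07. Their list, the PGC-1 family and nuclear receptor partners, had 12 of 28 genes higher and 5 lower (adjusted p = 0.024), and its call was lost with an estimated correlation (0.18) and without the genes whose probe sets disagreed. The transduced gene Ppargc1a, itself of the PGC-1 family, is among the genes whose probe sets disagreed. The ketone body enzyme Bdh1 had one of the largest rises of all, 36.7-fold (log2 5.20 ± 0.15, adjusted p = 2e-10), with a second probe set at log2 2.84. In its list of branched-chain amino acid, ketone and kynurenine metabolism, 17 of 28 genes rose and 2 fell, including rises of Got1 (3.57-fold) and Oxct1 (2.80-fold).

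The falls in A1 reached the regulators of muscle differentiation. Myog, the transcription factor myogenin, fell 4.36-fold (log2 -2.13 ± 0.06, adjusted p = 2.1e-10), from 3806 ± 256 to 859 ± 30.8. Mymx, which encodes a fusion peptide, fell 3.50-fold and Myod1 2.87-fold, though a second Myod1 probe set gave log2 0.01. Of 27 genes of myogenic regulators and fusion, 14 fell and 2 rose. Csrp3 fell 3.99-fold, Lmod2 3.67-fold and Tcap 3.20-fold in the common sarcomere, and Mybpc2 3.18-fold and Myh4 2.20-fold among fast fibre genes. Of 23 genes of calcium handling and excitation, 15 fell and 1 rose, with Camk2a down 2.27-fold and Jph1 2.26-fold. Of 16 slow fibre genes, in a list not called with an estimated correlation, 8 fell and 2 rose. Among these, Sln fell 4.82-fold at one probe set and gave log2 0.10 at another, and Myh7 fell 1.89-fold. Mamstr, a coactivator of muscle transcription, had the largest fall (5.02-fold, with log2 -0.69 at its other probe set), followed by Tmem94 (4.90-fold), Sln and Stac3 (4.60-fold). Of 22 heat shock and chaperone genes, 15 fell and 2 rose, with Hspb1 and Hspa1a each down 2.39-fold. Markers of extracellular matrix and fibroblasts fell in 14 of 33 genes and rose in 1, with Loxl1 down 3.64-fold (log2 -0.35 at its other probe set), but this list was not called with an estimated correlation (adjusted p = 0.18). In the cell cycle list 17 of 39 genes fell and 4 rose (adjusted p = 0.34 with an estimated correlation). The rises there included Gmnn (12.2-fold) and Rrm2 (3.01-fold). Markers of undifferentiated myoblasts went both ways, with 5 of 20 higher and 6 lower (adjusted p = 0.34).

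Against GFP, 5942 of 18193 genes differed in A1 at a limma adjusted p below 0.05, 3136 higher and 2806 lower. The share that was higher, 52.8%, was 45.4% after quantile normalization and 47.4% after median centring. Of these, 486 rose and 216 fell by at least 2-fold. Adjusted over the list alone, 74 respiratory chain genes and 48 mitochondrial ribosome genes rose, and 23 embryonic sarcomere and 15 myogenic genes fell. By camera with a preset correlation, 26 of 39 gene lists passed, 10 higher and 16 lower. The 9 that also passed with an estimated correlation were the TCA cycle (adjusted p = 0.004), fatty acid oxidation (0.011), mitochondrial DNA and import (0.004), branched-chain and ketone metabolism (0.019), embryonic sarcomere (0.0013), fast fibre (0.016), myogenic regulators (0.004), calcium handling (0.019) and heat shock (0.018). With that correlation the respiratory chain and the mitochondrial ribosome each had an adjusted p of 0.055 and the slow fibre list 0.098. Some of the largest rises rested on 1 probe set of several: Rmi1 went from 1.78 to 5950, Rnf144b from 13.6 to 4002, Vps35l from 97.8 to 7630 and Tnk1 from 90.0 to 4241. The other probe sets of these 4 genes changed by log2 values of at most 0.89.

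In A2 myotubes the changes were smaller and mostly downward, by a margin that depended on the scaling. Of the called changes of at least 2-fold, however, 59 were rises and 10 were falls. Genes of the sarcomere fell, from the embryonic and common set (19 of 26) to the slow fibre set (9 of 16) and the fast fibre set (6 of 15), and none of these rose. Heat shock genes fell in 13 of 22 cases and genes of the unfolded protein and integrated stress response in 15 of 38. The interferon response was the 1 list that clearly rose, with 9 of 36 genes higher and 1 lower.

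Myh4, the heavy chain of the fastest fibres, fell 2.40-fold in A2 (log2 -1.26 ± 0.09, adjusted p = 7.4e-06), from 753 ± 59.7 to 304 ± 12.8, and its other probe set gave log2 -0.41. Casq1 fell 1.44-fold. Csrp3 fell 1.82-fold, Ankrd1 1.54-fold and Ttn 1.46-fold, and among slow fibre genes Myh7 fell 1.72-fold and Myl2 1.43-fold. The call of Ttn ended without any 1 of the 3 A2 arrays or GFP array 1 or 3 (adjusted p = 0.061 to 0.13), and was 0.36 for the mean of its probe sets. In the myogenic list 9 of 27 genes fell and 1 rose, with Myf6 down 1.44-fold and Srf 1.42-fold, the latter with log2 0.00 at its other probe set. The heat shock genes Dnajb1, Hspb6 and Hspb1 fell 1.40-, 1.38- and 1.37-fold. The amino acid response genes Chac1 and Slc3a2 fell 1.52- and 1.51-fold. In cholesterol and fatty acid synthesis 16 of 30 genes fell and 2 rose, led by Acacb (1.71-fold, another probe set log2 0.42, adjusted p = 0.36 for their mean, and 0.062 to 0.074 without A2 array 1 or 3 or GFP array 2 or 3), Msmo1 (log2 -0.27 at its other probe set) and Nsdhl (1.51-fold each). In the TCA cycle list 10 of 20 fell and 1 rose, with Ogdh down 1.33-fold at one probe set and at log2 0.61 at another, which turns the direction of their mean (0.10). The antioxidant gene Txnrd1 fell 1.48-fold, and 7 of 22 antioxidant genes fell with none higher. Bst2, an interferon-induced membrane protein, rose 2.85-fold (log2 1.51 ± 0.12, adjusted p = 2.4e-05). Ifit2 rose 1.83-fold and Ifit1 1.75-fold. Tgm4 fell from 132 ± 2.74 to 11.1 ± 1.57, and no fold is given because the lower value lies below the added 16.

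In A2, 1796 of 18193 genes differed from GFP, 597 higher and 1199 lower, 59 and 10 of them by at least 2-fold. The share that was higher, 33.2%, was 45.3% after quantile normalization and 15.7% after median centring, and the count fell to 689 when only the 6 arrays compared were fitted. It was 1045, 1064 or 1107 without A2 array 1, A2 array 3 or GFP array 3. Adjusted over the list alone, 20 embryonic sarcomere, 16 heat shock and 23 stress response genes fell, and 11 interferon genes rose. By camera, 24 of 39 lists passed, 22 of them lower. With an estimated correlation 10 did: embryonic (0.0023), slow (0.0099) and fast sarcomere (0.018), myogenic regulators (0.017), heat shock (0.0094), unfolded protein response (0.018), cholesterol synthesis (0.041), TCA cycle (0.044), antioxidant defence (0.041) and the interferon response (0.0094), each an adjusted p. The 4 largest rises, Tnk1 (35.2-fold), Pde7a (32.2-fold), Troap (29.0-fold) and Nfkbia (23.1-fold), each came from 1 probe set, while the other probe sets of these genes lay between log2 -0.24 and 0.45.

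In A3 myotubes genes of the sarcomere and of stress responses fell, and genes of the interferon response rose. Of 36 interferon response genes, 17 rose and 1 fell. Embryonic and common sarcomere genes fell in 19 of 26 cases, slow fibre genes in 9 of 16 and fast fibre genes in 6 of 15. Heat shock genes fell in 14 of 22 cases and genes of the unfolded protein and integrated stress response in 21 of 38, and none in either list rose. Among mitochondrial ribosome genes 28 of 53 rose and 1 fell, without a call of that list at an estimated correlation (adjusted p = 0.29). Markers of other cells fell with the muscle genes: 8 of 33 matrix and fibroblast markers were lower and 1 higher (adjusted p = 0.0041, and 0.17 with an estimated correlation), and 6 of 20 markers of undifferentiated myoblasts were lower and 1 higher (0.012 and 0.083).

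Ifit1 rose 3.42-fold in A3 (log2 1.77 ± 0.12, adjusted p = 1.4e-06), from 407 ± 58.7 to 1423 ± 56.2. Ifit2 rose 2.79-fold and Rsad2 2.27-fold, the latter with log2 1.09 and 1.29 at its other probe sets. Hspa1a, the inducible heat shock protein 70, fell 2.81-fold (log2 -1.49 ± 0.08, adjusted p = 1.9e-07) and Hspa1b 2.27-fold, with 2 further Hspa1b probe sets at log2 -1.44 and -1.29. Csrp3 fell 2.79-fold, Ankrd1 1.90-fold and Tcap 1.85-fold. Myh4 fell 2.70-fold and Casq1 1.74-fold, and Myh7 fell 1.81-fold and Myl2 1.45-fold. In the myogenic list 10 of 27 genes fell and 1 rose: Nfatc2 rose 1.92-fold, though its 5 other probe sets lay between log2 -0.42 and 0.52, and Myf6 fell 1.80-fold. Mthfd2 fell 1.99-fold and Trib3 1.71-fold. Of 22 antioxidant genes 9 fell and 2 rose, with Txnrd1 down 2.34-fold (its other probe sets at log2 -1.03 and -0.78) and Hmox1 2.03-fold. Among angiogenic factors 8 of 28 fell and 2 rose, with the matricellular genes Ccn2 down 2.77-fold and Ccn1 1.75-fold. In the myostatin, activin, TGF-beta and BMP list 12 of 36 fell and none rose, including Id3 (1.75-fold). The prostaglandin synthase Ptgs2 fell 3.82-fold (log2 -1.93 ± 0.11, adjusted p = 5.2e-07) and log2 -1.57 at its other probe set. Mrpl11 rose 2.16-fold, with its other probe sets at log2 1.07, 1.13 and 0.68. Fatty acid genes went both ways, with Pdk4 down 1.94-fold and Lpl up 1.82-fold, and the list did not pass (5 of 29 higher and 5 lower).

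In A3, 3649 of 18193 genes differed from GFP, 2459 higher and 1190 lower, 66 and 24 of them by at least 2-fold. The share that was higher, 67.4%, was 53.6% after quantile normalization and 49.2% after median centring, and the count fell to 2042 when only the 6 arrays compared were fitted. Adjusted over the list alone, 20 embryonic sarcomere, 17 heat shock and 24 stress response genes fell, and 18 interferon genes rose. Of 39 lists 22 passed by camera, 20 of them lower, and 12 also with an estimated correlation. These were embryonic (adjusted p = 0.00068), slow (0.004) and fast sarcomere (0.004), myogenic regulators (0.004), heat shock (0.0029), unfolded protein response (0.004), interferon response (0.004), calcium handling (0.018), TGF-beta and BMP signalling (0.018), angiogenic factors (0.023), antioxidant defence (0.046) and thermogenic genes (0.047). The 4 largest rises, Tnk1 (29.5-fold), Nfkbia (21.0-fold), Pde7a (15.2-fold) and Troap (11.9-fold), again came from 1 probe set of each gene, with log2 values of -0.24 to 0.44 at the others.

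A4 myotubes, the group labelled with hypertrophy, had higher signals for genes of the respiratory chain, the mitochondrial ribosome and fatty acid oxidation and for several muscle genes, and lower heat shock genes. With an estimated correlation none of these lists was called (adjusted p of 0.35, 0.35, 0.23 and, for heat shock, 0.059). Of 75 respiratory chain and ATP synthase genes 58 rose and none fell, as did 36 of 53 mitochondrial ribosome genes and 19 of 29 fatty acid genes. Among genes of mitochondrial DNA, import and dynamics 7 of 31 rose and 7 fell, and that list did not pass (adjusted p = 0.999). Of 22 heat shock genes 16 fell and 4 rose. In the slow and fast fibre lists 6 of 16 and 6 of 15 genes rose, and 1 slow fibre gene fell, but neither list passed camera (adjusted p = 0.055 and 0.094).

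Cox7a1 rose 3.10-fold in A4 (log2 1.63 ± 0.09, adjusted p = 1.9e-07), Uqcrq 1.74-fold at one of 4 probe sets, and Cox8b 1.73-fold. Mrps16 rose 2.15-fold and Mrps36 1.76-fold. Pdk4, which restrains pyruvate oxidation, rose 1.78-fold and Fabp3 1.69-fold, the latter with log2 0.04 at its other probe set. Perm1, Sirt3 and Esrra rose 2.32-, 2.15- and 1.97-fold, and the other probe set of Perm1 gave log2 0.14. Of 28 genes of branched-chain amino acid and ketone metabolism 17 rose and 1 fell, led by Bckdhb (1.83-fold) and Hibch (1.49-fold). This list was not called with an estimated correlation. Pln, which regulates the calcium pump of slow fibres, rose 2.36-fold (log2 1.24 ± 0.07, adjusted p = 2.4e-07), with log2 1.10 and 0.93 at its other probe sets. Myl2 rose 1.97-fold and Myh7 1.87-fold. Myh4 rose 1.97-fold, with log2 0.29 at its other probe set, and Mymx 2.77-fold (log2 1.47 ± 0.15, adjusted p = 2.1e-05). Myog rose 1.68-fold, from 3806 ± 256 to 6394 ± 197, and Csrp3 1.99-fold, while Xirp1 fell 1.69-fold. Hspa1a fell 9.33-fold (log2 -3.22 ± 0.08, adjusted p = 2.5e-10), from 7460 ± 674 to 784 ± 42.7. Hspa1b fell 5.41-fold with all 3 probe sets in the same direction, Dnajb1 2.61-fold and Hsph1 2.11-fold. Of 38 genes of the unfolded protein and integrated stress response 17 fell and 2 rose, including Ppp1r15a (1.94-fold) and Atf4 (1.92-fold, with log2 -0.40 and 0.16 at its other probe sets). That list was not called with an estimated correlation either.

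Secreted and inflammatory genes moved in A4, without a call for the inflammatory list or the matrix list. Lcn2, or lipocalin 2, rose from 13.6 ± 7.14 to 237 ± 36.0 (adjusted p = 3.8e-05), and Saa3, a serum amyloid gene, 4.04-fold. Ptgs2 fell 5.33-fold and log2 -1.60 at its other probe set. In the inflammatory and NF-kB list 10 of 38 genes rose and 7 fell (adjusted p = 0.62). Col1a1 rose 2.50-fold and log2 2.62 at its other probe set, and Pdgfrb 1.89-fold, with log2 0.42 at its other probe set. Of 33 matrix and fibroblast markers 7 rose and 5 fell (adjusted p = 0.48). In the myostatin, activin, TGF-beta and BMP list 4 of 36 genes rose and 11 fell, with Fstl1 up 2.43-fold and Smad7 down 2.11-fold, and the call of that list (adjusted p = 0.028) was lost with an estimated correlation (adjusted p = 0.35). Igf1 did not pass in A4: its log2 difference from GFP was 0.03 ± 0.08 (adjusted p = 0.81), and the IGF1, AKT and mTOR list had 7 of 31 genes higher and 11 lower (adjusted p = 0.26).

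In A4, 5429 of 18193 genes differed from GFP, 3184 higher and 2245 lower, 119 and 118 of them by at least 2-fold. The share that was higher, 58.7%, was 45.6% after median centring, and the count fell to 3355 when only the 6 arrays compared were fitted. Adjusted over the list alone, 66 respiratory chain and 37 mitochondrial ribosome genes rose, and 16 heat shock genes fell. By camera 12 of 39 lists passed, 8 higher and 4 lower, and none passed with an estimated correlation. There the adjusted p was 0.35 for the respiratory chain and for the mitochondrial ribosome, 0.23 for fatty acid genes, 0.16 for branched-chain metabolism and for the unfolded protein response, and 0.059 for heat shock. The rises of Rnf144b (from 13.6 to 4484, no fold given as the former lies below the added 16), Tnk1 (38.0-fold) and Grin2d (10.2-fold) came from 1 probe set of each gene, with log2 values between -0.02 and 0.45 at the others. The falls of Atl3 (5.65-fold) and Sp6 (5.05-fold) likewise came from 1 probe set each, and another Sp6 probe set rose by log2 4.67.

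**Figure D3:**
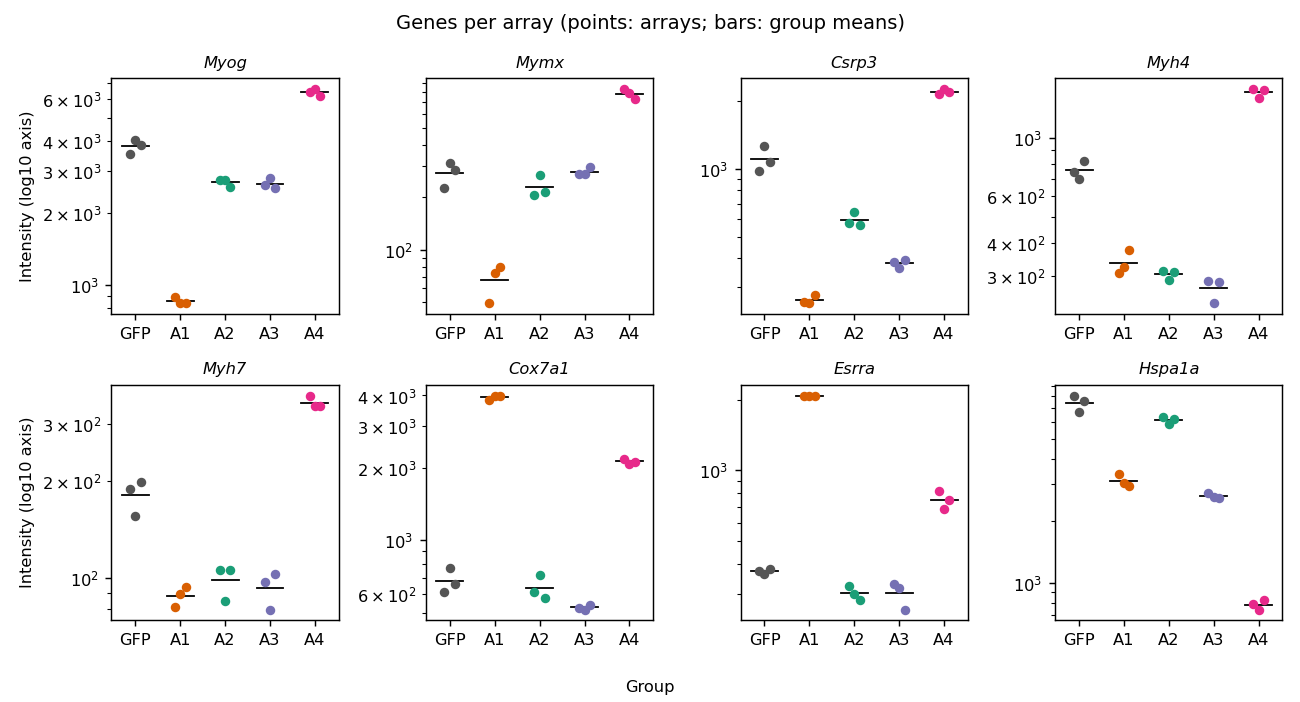
Intensity of 8 genes on each of the 15 arrays, on log10 axes, with 1 point per array and a bar at the mean of each group. Myog, Mymx and Csrp3 lie lowest in A1 and highest in A4. Myh4 and Myh7 lie below GFP in A1, A2 and A3 alike and are highest in A4. Cox7a1 and Esrra are highest in A1, and Hspa1a falls from 7460 in GFP to 784 in A4.

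The direct comparison of A4 with A1 set the group with hypertrophy against the isoform with the largest mitochondrial change. Muscle genes were higher in A4 across all 4 muscle lists, and mitochondrial genes were lower, though the respiratory chain and mitochondrial ribosome lists were not called with an estimated correlation (adjusted p = 0.25 each). Of 27 myogenic genes 17 were higher and 1 lower, of 26 embryonic and common sarcomere genes 20 were higher, of 16 slow fibre genes 13 were higher and 1 lower, and of 15 fast fibre genes 10 were higher. Conversely 57 of 75 respiratory chain genes, 25 of 31 genes of mitochondrial DNA and import, 23 of 29 fatty acid genes and 17 of 20 TCA cycle genes were lower in A4.

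Mymx was 9.70-fold higher in A4 than in A1 (log2 3.28 ± 0.15, adjusted p = 5e-09), at 784 ± 50.8 against 67.5 ± 15.9. Csrp3 was 7.94-fold, Mamstr 7.80-fold, Rrad 7.47-fold and Myog 7.33-fold higher, with log2 1.44 at the other Mamstr probe set. Among fast fibre genes Myh4 was 4.32-fold and Mybpc2 4.30-fold higher, and among slow fibre genes Sln 3.56-fold (log2 0.38 at its other probe set) and Myh7 3.53-fold. Tcap (4.99-fold), Lmod2 (4.51-fold), Jph2 (2.43-fold) and Cacng1 (2.31-fold) were higher as well. Lower in A4 were Bdh1 (32.8-fold), Tesc (25.2-fold), Cpt1a (4.07-fold), Ogdh (2.64-fold), Dlat (2.28-fold), Gabpa (3.09-fold) and Timm8a1 (3.04-fold), and the other probe sets of these 7 genes were also lower. Cox7a1, which rose over GFP in both groups, was 1.85-fold lower in A4 than in A1 (adjusted p = 3.5e-06). The stress genes Ppp1r15a and Atf3 were 2.88- and 2.83-fold lower in A4, with 24 of 38 genes of that response lower and 5 higher. Of 15 smooth muscle and pericyte markers 6 were higher and none lower, with Smtn at 2.58-fold. Of 33 matrix and fibroblast markers 15 were higher and 1 lower, including Loxl1 (3.39-fold, and log2 0.30 at its other probe set), but that call was lost with an estimated correlation (adjusted p = 0.17).

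Between A4 and A1, 7245 of 18193 genes differed, 3694 higher and 3551 lower in A4, 412 and 449 of them by at least 2-fold. Adjusted over the list alone, 21 embryonic sarcomere and 17 myogenic genes were higher and 62 respiratory chain genes lower. By camera 20 of 39 lists passed, and 10 with an estimated correlation. These were TCA cycle (adjusted p = 0.011), fatty acid oxidation (0.041), mitochondrial DNA and import (0.0091), myogenic regulators (0.0078), fast (0.016), slow (0.022) and embryonic sarcomere (0.0051), calcium handling (0.044), the unfolded protein response (0.048) and smooth muscle markers (0.041). The respiratory chain and mitochondrial ribosome lists each had an adjusted p of 0.25 with that correlation. The differences in Rmi1 (1.13 in A4 and 5950 in A1, again without a fold) and Vps35l (68.0-fold) lay in 1 probe set of each gene.

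Set against the mean of A1, A2, A3 and GFP, A4 had higher signals for most muscle genes, while mitochondrial lists went both ways without a call at an estimated correlation. Of 26 embryonic and common sarcomere genes 19 were higher and 1 lower, of 27 myogenic genes 18 were higher and 2 lower, of 16 slow fibre genes 11 and of 15 fast fibre genes 10 were higher with none lower. Of 75 respiratory chain genes 43 were higher and none lower (adjusted p = 0.51 with an estimated correlation), while among genes of mitochondrial DNA and import 6 of 31 were higher and 16 lower (adjusted p = 0.20 with that correlation). Markers of other cells were higher along with the muscle genes: 12 of 33 matrix and fibroblast markers with 2 lower (adjusted p = 0.0092, and 0.26 with an estimated correlation), and 7 of 15 smooth muscle and pericyte markers with none lower (0.013 and 0.10).

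Csrp3 was 4.22-fold higher in A4 than this mean (log2 2.08 ± 0.07, adjusted p = 1.5e-09), Mymx 3.93-fold and Myh4 3.82-fold (log2 0.92 at its other probe set). Myh7 was 2.91-fold, Myog 2.89-fold, Tcap 2.63-fold, Pln 2.61-fold and Myl2 2.20-fold higher. Lcn2 was also higher (adjusted p = 1.1e-05), and Grin2d was 4.68-fold higher at 1 of its 2 probe sets. The glycogen synthase Gys1 was 1.52-fold and the glucose transporter Slc2a4 1.39-fold higher (adjusted p = 0.34 against the pooled arrays), and of 27 genes of glucose use 20 were higher and 1 lower (adjusted p = 2.7e-05, and 0.26 with an estimated correlation). Hspa1a was 5.53-fold lower, and Atl3 5.54-fold lower at 1 of 5 probe sets. In all 6483 of 18193 genes differed, 3481 higher and 3002 lower, and 2747 when A4 was set against 1 pooled group of the other 12 arrays. Adjusted over the list alone, 19 embryonic sarcomere, 18 myogenic, 12 slow fibre and 11 fast fibre genes were higher. By camera 16 lists passed, and 4 with an estimated correlation: embryonic sarcomere and myogenic regulators (adjusted p = 0.016 each) and slow and fast fibre (0.022 each). Of 100 groupings of the 15 arrays, the real one included, 12 gave at least as many lists as the real one, and up to 19. Such groupings can still carry differences between the real groups, so they do not show how many lists chance alone would give. Chance is thus not excluded for the number of lists. For genes the highest other grouping gave 17, but mixing arrays of different groups lowers that count.

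Genes that set 1 group apart from each of the other 4 were counted where all 4 direct contrasts passed with the same sign. There were 2914 for A1 (1497 higher and 1417 lower), 1783 for A4 (870 and 913), 620 for A3 (570 and 50), 275 for GFP (164 and 111) and 143 for A2 (39 and 104). After quantile normalization the split for A2 turned to 61 higher and 41 lower, for A1 to 1416 and 1735, and with only the 2 groups fitted for A2 to 31 and 17. For A4 it turned to 836 and 647 with the mean of probe sets, to 952 and 922 with 64 added, and to 828 and 822 without GFP array 3. For GFP it was 251 and 61 after median centring. In A1 Bdh1 was at least 30.1-fold above and Stac3 at least 3.71-fold below every other group. In A4 Hspa1a was at least 3.32-fold below. In A3 Ifit1 was at least 1.95-fold above each other group, and in A2 Rapgef3 was at least 3.35-fold above at 1 probe set of 5, with Tmem175 at least 2.36-fold below at 1 of its 2 probe sets (the other gave log2 0.07 against GFP). Ptgs2 and Ccn2 were highest in GFP, by at least 1.68- and 1.55-fold, while Tnk1, Armc9, Pik3cd and Tifa were lowest there. The first 3 of these rest on 1 probe set each, as their other probe sets moved on average by log2 -0.44 to 0.40 in the 4 isoforms. When only the 2 groups of each contrast were fitted, the counts were 48 for A2, 364 for A3, 1154 for A4 and 76 for GFP. Without A2 array 1 or 3, A3 array 1 or GFP array 3 the count for A2 was 68, 75, 95 or 92, and the latter 2 arrays also lowered A3 to 370 and GFP to 182.

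The remaining contrasts between isoforms placed A2 and A3 closest to each other. Between A2 and A3 2636 genes differed, 447 higher and 2189 lower in A2, a share of 17.0% higher that became 43.0% after quantile normalization. The count was 1561, 1540 or 1552 without A2 array 1, A2 array 3 or A3 array 1. A4 differed from A2 in 5588 genes (3356 higher) and from A3 in 5381 (2400 higher). A1 differed from A2 in 5686 genes (2983 higher) and from A3 in 6316 (2579 higher). The share higher moved from 60.1% to 48.3% for A4 over A2 and from 52.5% to 41.8% for A1 over A2 after quantile normalization.

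A1 and A4 changed 1979 genes in the same direction against GFP, 1233 up and 746 down, where independent calls would share 549 and 346. The split turned to 1027 up and 1066 down after quantile normalization and to 887 and 930 after median centring. They also changed 888 genes in opposite directions, where independent calls would give 878. Mymx, Rrad, Csrp3, Top2a and Myh4 are among them: Rrad gave log2 -1.73 in A1 and 1.17 in A4, and Top2a -0.98 and 1.04, while the other Top2a probe sets gave -0.41 and -0.34 in A1 and 0.07 and -0.26 in A4. A2 and A3 shared 1051 genes, with 5 opposite where independent calls would give 201. A3 and A4 shared 1378 with 569 opposite, A1 and A3 1620 with 565, A1 and A2 972 with 283, and A2 and A4 595 with 367. Without A2 array 1 or 3 the count for A1 and A2 was 636 or 646, and for A2 and A4 346 or 348, with 386 without A2 array 2 and 340 without GFP array 3. In A2 and A4 the opposite genes included Myh4, Csrp3 and Myh7. In A3 and A4 they included Rsad2, which gave log2 1.18 and -1.05. All 4 contrasts share the 3 GFP arrays, which alone gives a correlation of 0.50 between log2 changes in simulated data without effects. The correlation across genes was 0.617 for A2 and A3 and between 0.305 and 0.384 for the other pairs. The covariance was 0.0294 to 0.0505 over the 6 pairs, against 0.0139 simulated without effects. Simulated overlaps of calls were at most 0.02 genes on average. Data without effects yield almost no calls, so this does not show how many shared calls come from the shared GFP arrays.

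The genes fixed in advance as known targets or muscle markers differed between isoforms. Vegfa rose 2.65-fold in A1 (log2 1.41, second probe set 1.65), fell in A2 (log2 -0.34) and A3 (-0.59), and gave 0.11 in A4 (adjusted p = 0.38, but 0.35 with adjusted p = 0.0020 for the mean of its probe sets). Its call in A2 ended without any 1 of the A2 arrays or GFP array 2 or 3 (adjusted p = 0.052 to 0.078). Tfam rose in A1 (log2 0.99, second probe set 0.13) and gave -0.10, 0.14 and 0.01 in A2, A3 and A4 with no call. Cycs rose in A1 (0.70), fell in A2 (-0.22, not called without A2 array 1 or GFP array 3, adjusted p = 0.071 and 0.056) and was not called in A3 (-0.08) or A4 (0.10, but 0.32 with adjusted p = 0.0040 for the mean of its probe sets). Slc2a4 rose in A1 (1.03) and A4 (0.60), fell in A2 (-0.37), and gave -0.19 in A3 (adjusted p = 0.086). Pdk4 rose in A1 (0.62) and A4 (0.84) and fell in A2 (-0.69) and A3 (-0.96). Esrra fell in A3 (-0.31, adjusted p = 0.031, but 0.053 to 0.11 without A3 array 3 or any 1 GFP array) and gave -0.30 in A2 (0.058). The ubiquitin ligase genes of muscle atrophy fell in A1, Trim63 by log2 -1.35 and Fbxo32 by -0.67 (-0.15 and -0.30 at its other probe sets). In A4 Trim63 rose (0.35, adjusted p = 0.00017) and Fbxo32 gave -0.11 (0.30, but -0.16 with adjusted p = 0.049 for the mean of its probe sets). Igf1 rose in A3 (0.43 ± 0.08, adjusted p = 0.0026, with its 3 other probe sets between -0.17 and 0.15 and an adjusted p of 0.37 for the mean of all 4) and was not called in A1 (-0.13), A2 (0.09) or A4. Ppargc1b fell in A1 (-1.02) and was not called elsewhere. Ucp3 was called in no isoform (adjusted p of 0.20 or more), and Fndc5 was called in A4 (0.30, adjusted p = 0.0024). In A1 Fndc5 gave 0.15 (0.072), but 0.27 with adjusted p = 0.013 for the mean of its probe sets, and it was also called there in 4 other settings (0.036 to 0.044). Such calls in some settings only were also seen for Tfam and Slc2a4 in A3 and for Esrra and Ppargc1b in A2.

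**Figure D4:**
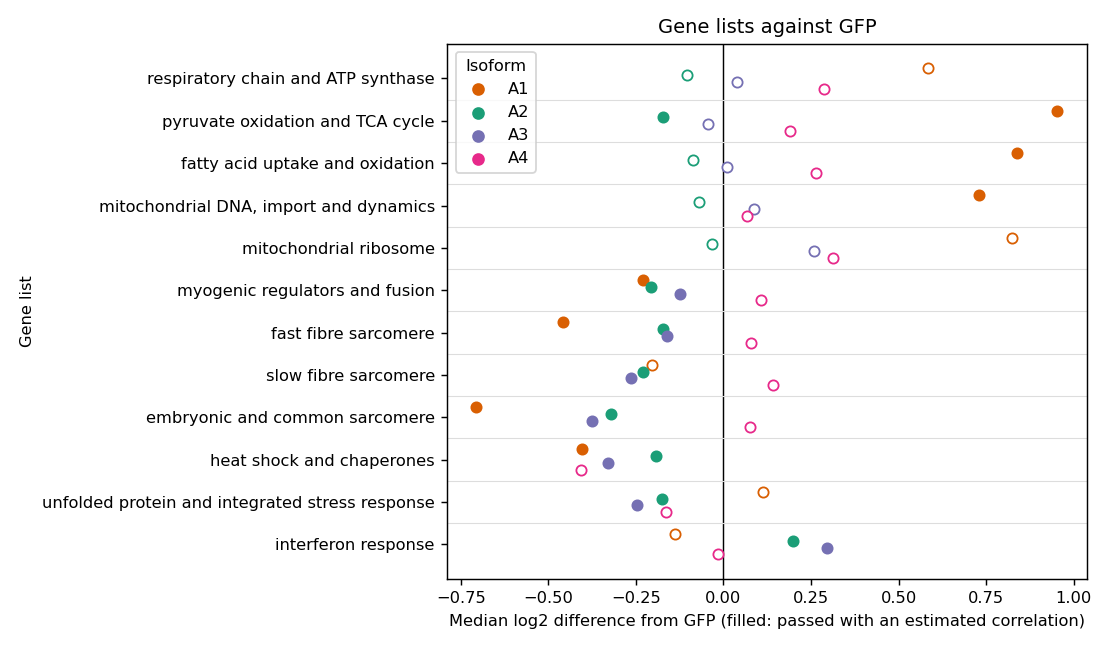
Median log2 difference from GFP of the measured genes of 12 gene lists in A1, A2, A3 and A4, 1 point per list and isoform; filled points passed camera with an estimated correlation, open points did not. The TCA cycle list has a median of 0.95 in A1 and 0.19 in A4, and the embryonic sarcomere list -0.71 in A1 and 0.08 in A4.

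Genes with several probe sets allowed a check of the largest changes. Among genes that rose at least 2-fold in A1, 230 had another probe set with a mean intensity of at least 50, and in 153 (66.5%) the others moved at least 50% as much. The corresponding numbers were 0 of 13 in A2, 5 of 20 in A3 and 7 of 31 in A4. A strong rise helps a probe set to be the brightest and so to be chosen, which favours smaller changes at the others. For falls of at least 2-fold the numbers were 59 of 98 in A1, 0 of 4 in A2, 5 of 6 in A3 and 14 of 53 in A4. Changes of any size were also compared, without the floor of 50, where the chosen and another probe set were both called. Over GFP these moved in opposite directions in 5.92% of cases in A1, 8.08% in A2, 4.6% in A3 and 12.5% in A4 (224 of 1785). The share was 13.6% for A4 over A1 and 17.5% (486 of 2771) for A4 over the mean of the others.

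**Figure D5:**
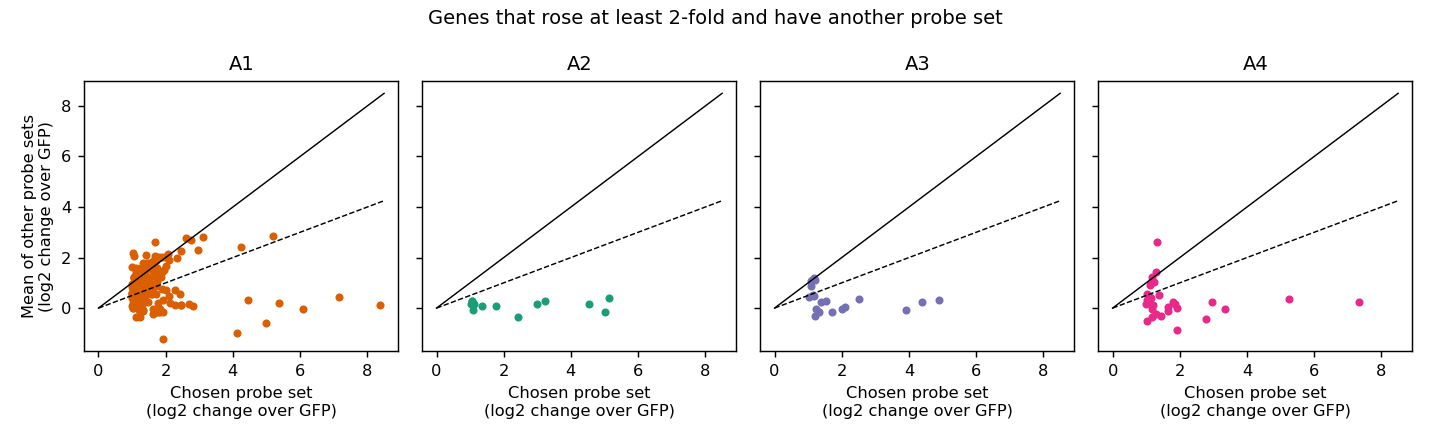
For genes that rose at least 2-fold over GFP and have another probe set, the log2 change of the chosen probe set (horizontal axis) and the mean log2 change of the others (vertical axis), 1 point per gene and 1 panel per isoform; the solid line marks equal change and the dashed line 50% of it. In A1 153 of 230 genes lie on or above the dashed line, in A2 0 of 13, in A3 5 of 20 and in A4 7 of 31.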

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

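All tests of explanations in this part were chosen after the results were seen, and so were their limits. Some results were marked because 2 isoforms moved the same gene in opposite directions against GFP, which makes their direct difference pass by construction. There were 283 such genes for A1 and A2, 565 for A1 and A3, 888 for A1 and A4, 5 for A2 and A3, 367 for A2 and A4 and 569 for A3 and A4. Independent calls would give 299, 584, 878, 201, 284 and 512, so most of these counts lie near that number, and that of A2 and A3 lies far below it. The shared GFP arrays favour changes in the same direction. Nearness to that number therefore does not mark opposite calls as chance. Others stood out because signal changed in probe sets without a single gene name, which the comparisons of genes do not use. Of 10092 such probe sets, 698 were called higher over GFP in A1, 203 in A2, 443 in A3 and 709 in A4. Lower were 539 in A1, 163 in A2, 252 in A3 and 539 in A4.

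The first pattern weighed is that many of the largest rises rest on 1 probe set. Where the whole transcript pool of a gene rises, its other probe sets should rise too, and in A1 153 of 230 genes did so, which argues against a single-probe-set signal as the general cause there. In A2, A3 and A4 only 0 of 13, 5 of 20 and 7 of 31 did, so among these most may be signals of a single probe set. The shares cannot settle this, because the chosen probe set is the brightest over all arrays. A strong rise helps a probe set to be chosen, which favours smaller changes at the others. The rest of the 59, 66 and 119 rises could not be checked this way. A fall lowers the mean of a probe set and so works against its choice. Yet by the same measure the others followed in only 14 of 53 falls of at least 2-fold in A4. Their median log2 change was -0.094, against -1.12 at the chosen probe sets. This argues against the choice of the brightest as the cause for the falls in A4. The others followed in 59 of 98 falls in A1, 0 of 4 in A2 and 5 of 6 in A3. For the rises the question stays open. Tnk1 rose in all 4 isoforms at 1 probe set, while Rmi1 and Vps35l rose in A1 only, so the virus that carried the isoform, a transcript variant and cross-hybridisation all stay open, and the sequences of probes and viruses were not used here.

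The second pattern is the fall of heat shock genes in A4, which was as large in A1 (median log2 -0.40, and -0.41 in A4) and was also seen in A2 (-0.19) and A3 (-0.33), and 8 of 22 genes were lower in all 4 isoforms, each of which also differed between at least 2 isoforms. On the third principal component the GFP arrays alone lay between -27.4 and -18.6 and all others at -2.00 or above. A fall shared by all isoforms cannot be told apart from GFP arrays that stand apart, because there is 1 control group. The difference between A4 and A2 uses no GFP array by construction, so it does not test this explanation. It was called in 16 of 22 heat shock genes, 12 lower and 4 higher, against 30.7% of all genes. Directly against A1 the list did not pass (10 lower and 7 higher, adjusted p = 0.42), against A3 11 were lower and 8 higher, stress from infection or handling was not tested, and an effect of the isoform stays open.

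The third pattern is the fall of muscle genes in A1. A lower share of muscle cells should raise markers of other cells, but 14 of 33 matrix and fibroblast markers were lower and 1 was higher. More dividing myoblasts should raise cell cycle genes, but 17 of 39 were lower and 4 were higher. Neither list passed with an estimated correlation (adjusted p = 0.18 and 0.34), and muscle cells also express matrix genes, so both explanations cannot be told apart from an effect of the isoform.

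Whether chance can be excluded was checked by regrouping the arrays. For each pair of groups only 10 splits exist, too few for a share below 0.1. In each pair only the real split, 1 of 10, reached its number of genes. The highest other split gave 0 genes against 5942 for A1, 0 against 1796 for A2, 1 against 3649 for A3 and 1 against 5429 for A4, all over GFP. It gave 6 against 7245 for A4 and A1, 0 against 5588 for A4 and A2, 0 against 5381 for A4 and A3, 1 against 5686 for A1 and A2, 1 against 6316 for A1 and A3, and 0 against 2636 for A2 and A3. For lists the real and highest other numbers lay closer, at 26 and 16 for A1, 24 and 17 for A2, 22 and 19 for A3, 12 and 8 for A4, and 20 and 15 for A4 over A1.

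Of 100 regroupings of all 15 arrays, only the real one reached the 6483 genes of A4 against the other 4 groups (highest other 17). Mixing arrays of different groups widens the spread within groups and lowers such counts. Low counts thus speak against arrays that do not differ by group at all, but do not exclude chance for 1 contrast or between cultures. For the 16 lists of A4 against the other 4 groups, 12 of 100 regroupings gave as many, up to 19, so chance is not excluded there either. For genes that set a group apart, only the real grouping reached the counts of A1 (2914, highest other 0), A4 (1783, highest other 0) and GFP (275, highest other 15). For A2 and A3, 2 of 100 regroupings reached the real 143 and 620, the real one included, and the other gave 800 and 713. In both of these the 3 A4 arrays stood together as the group set apart, and in both the 3 GFP arrays stayed together, so the counts point to a structure of the samples. The overlaps were each reached by 1 of 100, the real one: A1 and A2 972 (highest other 72), A1 and A3 1620 (58), A1 and A4 1979 (60), A2 and A3 1051 (361), A2 and A4 595 (59), and A3 and A4 1378 (25). Mixed groups give few calls and so little overlap, so chance is not excluded for a single pair.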

How the results depend on the processing

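The tests measure called differences in array signal above an unstated background, so dim genes and transcripts outside the probes stay unseen. With a correlation estimated per list, the lists past the threshold fell to 9 for A1, 10 for A2, 12 for A3 and 0 for A4 over GFP, 10 for A4 over A1 and 4 for A4 over the rest, since genes of a list vary together between arrays. With fry they were 23 for A4, 33 for A4 over A1 and 28 for A4 over the rest. With only the groups compared, which leaves fewer arrays for the variance, 689 genes were called in A2, 2042 in A3 and 3355 in A4. A4 over the rest gave 2747 against 1 pooled group, whose variance includes the differences between its 4 groups. Then 48 genes set A2 apart, 364 A3, 1154 A4 and 76 GFP, and the overlaps were 391 (A1 and A2), 862 (A1 and A3), 1149 (A1 and A4), 392 (A2 and A3), 153 (A2 and A4) and 565 (A3 and A4). Testing all 45037 probe sets counts a gene more than once and gave 11048 calls in A1, 2824 in A2, 6043 in A3 and 9765 in A4. It gave 14200 for A4 over A1, 10502 for A4 over A2, 9896 for A4 over A3, 10291 for A1 over A2, 11582 for A1 over A3 and 12458 for A4 over the rest. Probe sets that set A1 and A4 apart numbered 5022 and 3104, and overlaps were 1568 (A1 and A2), 2655 (A1 and A3), 3216 (A1 and A4), 1643 (A2 and A3) and 2166 (A3 and A4). The 143 genes that set A2 apart became 79 with the mean of probe sets, 229 without the dimmest genes, 264 with a trend and robust and 224 with array weights, and the cause was not tested. The mean of probe sets turned the direction of Ogdh in A2 (0.10), Sp6 in A4 (0.53) and Ppargc1a in A4 (0.075), because the probe sets of these genes differ. It also ended 6 calls of named genes, among them Ttn, Acacb and Cycs in A2 and Igf1 in A3, and gained 5. Only the groups compared ended 8 such calls, all probe sets 2, quantile normalization 2 and an added value of 1 ended 1. Without the dimmest genes 5 were gained, with a trend and robust 5, after median centring 3, and 1 each with an added value of 1 or 64 and after quantile normalization. Leaving out 1 array ended calls 34 times and gained 3. Leaving out 1 array, with 2 left in that group, gave 5212 to 6113 genes in A1, 1045 to 1923 in A2, 2697 to 3822 in A3 and 4615 to 5454 in A4. It gave 6321 to 7384 for A4 over A1, 4683 to 5719 for A4 over A2, 4451 to 5497 for A4 over A3, 4829 to 5890 for A1 over A2, 5547 to 6502 for A1 over A3, 1540 to 2766 for A2 over A3 and 5403 to 6578 for A4 over the rest. Genes that set groups apart ranged from 2529 to 2869 (A1), 68 to 142 (A2), 370 to 634 (A3), 1458 to 1727 (A4) and 182 to 271 (GFP). Overlaps ranged from 636 to 1032 (A1 and A2), 1259 to 1691 (A1 and A3), 1716 to 1936 (A1 and A4), 723 to 1098 (A2 and A3), 340 to 646 (A2 and A4) and 1078 to 1379 (A3 and A4). Lists ranged from 23 to 26 (A1), 22 to 25 (A2), 21 to 23 (A3), 10 to 14 (A4), 18 to 21 (A4 over A1) and 15 to 16 (A4 over the rest). The replicate number as a block gave 5796, 1573, 3425 and 5254 genes in A1 to A4 and changed no named call but that of Ppargc1a in A4 (adjusted p = 0.053). The numbers showed no general pairing in the data: 2 of 30 same-number pairs had an r above 0.1, and 6 of 15 arrays lay closest to their own number. Both of these pairs were arrays numbered 1, A1 with A4 (0.168) and A3 with A4 (0.135), so a link among some of them is not excluded. Pairs of unlike number reached similar values, such as A1 array 3 with A4 array 2 (0.142). The alternative added after the data were seen moved no count of genes, overlaps or lists by over 1.5 times.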

Other observations

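Genes of glucose use were called in both directions against GFP. In A1 13 of 27 were higher and 5 lower, with Ldhb up 4.19-fold at all 4 probe sets and Hk1 3.46-fold, and in A4 14 were higher and 2 lower, led by Slc2a4 (1.51-fold), Pgam1 (1.49-fold) and Hk1 (1.47-fold). In A2 15 were lower and none higher, and in A3 10 were lower and 2 higher, with Hk2 down 1.37- and 1.58-fold and Gys1 1.29-fold in each. None of these lists passed with an estimated correlation (adjusted p of 0.10 to 0.49), and directly between A4 and A1 the list did not pass either (adjusted p = 0.76). Of 20 neuromuscular junction genes 13 fell and 4 rose in A1, 9 fell and none rose in A2, and 10 fell and 1 rose in A3, and Musk, a receptor kinase of the junction, fell 2.74-, 1.63- and 1.68-fold. In A4 8 fell and 2 rose. The calls of this list were lost with an estimated correlation (adjusted p of 0.17, 0.10, 0.096 and 0.49 in A1 to A4). Of 23 p53 targets 15 were lower and 1 higher in A1, with Eda2r down 2.13-fold (adjusted p of the list 0.055 with an estimated correlation).

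Markers of endothelial cells, macrophages, adipocytes and Schwann cells passed in none of the 4 isoforms by camera, with adjusted p of 0.14 or more. Whether the sarcomere genes follow the hypertrophy that the labels record cannot be read from 5 groups, because hypertrophy and A4 coincide. By camera with the preset correlation, 4 muscle lists were higher in A4 than in the mean of the others and lower in A1, A2 and A3 than in GFP, while over GFP itself A4 passed in none of these 4. With an estimated correlation the slow fibre list in A1 was not called (adjusted p = 0.098). Of the 16 lists in that contrast, 4 passed with an estimated correlation, and 12 of 100 regroupings gave as many as 16 lists. Morphology of the same cultures was not analysed here.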
